A study of Homo sapiens with 24 samples.

How the data were processed

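The study measured RNA in MCF7 cells of 4 subclones kept at 20% or 1% O2 for 24 hours, with 3 biological replicates per group and 24 libraries. Total RNA was extracted with TRIzol and sequenced on a NovaSeq instrument, per the labels' protocols. FastQC, STAR, featureCounts and the GRCh38 genome are named in the submitters' processing notes, without versions, and annotation of Ensembl release 100 per the file headers and names. The deposited table holds TPM, transcript levels scaled to a total of 1000000 per library, for 60683 genes. The authors also deposited 3 gene lists they had chosen on these libraries, 2 of hypoxia-induced genes and 1 of hypoxia-repressed genes, and a ratio by the authors between oxygen levels in the HIF-1-dependent list, which was not used. The deposited column names mark all 3 knockdowns with the letters DKD, which the labels do not explain, so what the shHIF-1α subclone carries beside a hairpin against HIF-1α is unknown. The gene length behind the TPM, the strand setting and the authors' tests were not stated. Without a stated strand setting, reads of overlapping or antisense genes could not be told apart, and near-identical copies such as the LDHA pseudogenes can share reads.

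Read numbers were rebuilt from the smallest step of each TPM column: all 36625 genes above 0 in at least 2 libraries came out as whole reads within 0.001 of a read. The totals, 23.2 M to 39.6 M with a median of 31.6 M, are lower bounds of the depth per library. Each gene was rebuilt up to a common divisor, and 5085 genes above 0 in 1 library only were counted as 0. Correlations between replicates lay between 0.9922 and 0.9985 over 24 pairs, and no pair looked like a repeat of the same library (mean chi-square per gene 2.01 to 31.07).

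Genes with at least 1 TPM in at least 3 libraries were tested, 20687 genes holding at least 99.72% of TPM in every library; 39996 genes were left out as too low. Values were log2(TPM + 1). The limma package fitted 8 group means to all 24 libraries, with 16 residual degrees of freedom and a moderated spread (trend and robust), for 13 contrasts: 1% against 20% O2 in each subclone, each knockdown against shNTC at each oxygen level, and the interactions, the response to 1% O2 in a knockdown minus that in shNTC. P values are two-sided, adjusted over all genes of a contrast by Benjamini-Hochberg, and a gene was called at 0.05. The SE is that of the moderated fit.

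The design, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. There were 26 lists with 535 genes, covering the oxygen response, metabolism, proliferation, stress and immune signalling, chromatin and lineage markers. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated per list; a list's own members were also adjusted over the list alone. The rule named the knockdown targets, the sentinel hypoxia genes, the 10 called genes with the largest rise and the 10 with the largest fall per contrast (with at least 5 TPM in the higher group and, outside interactions, replicates that did not overlap), and the 4 members of a described list with the smallest p. Other genes are named as chosen after their values were seen, apart from the levels and changes in other groups of a gene the rule named. Positions are from GENCODE 29 on GRCh38, matched by Ensembl identifier.

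Induced genes were those called at least 1.5-fold higher at 1% O2 in shNTC; induction counted as reduced where the interaction was called below 0. The median ratio expected from that selection alone came from 20 simulations of knockdowns without any effect. Overlaps between knockdowns were set beside the product expected of independent lists and beside simulated unchanged knockdowns sharing the shNTC libraries.

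The steps were tested on simulated data made from 17641 genes. For the response in shNTC, 89.6%, 95.5% and 98.5% of genes changed 1.5-, 2- and 4-fold were called, with 0.09% of unchanged genes. For shFACT against shNTC at 1% O2 the shares were 92.5%, 95.5% and 98.5%, with 0.1% of unchanged genes, and for the interaction of shFACT 70.1%, 91% and 98.5%, with 0.07%. Each share of changed genes rests on 66 or 67 genes. The real fit held 20687 genes, so the shares need not hold for all genes tested. For the response in shFACT, 0 of 17441 unchanged genes were called in the simulation. Another grouping of the real shFACT libraries called 1908 genes. The shares of unchanged genes called may therefore be too low for the real libraries.

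Alternatives were other pseudocounts, other low-value filters, median-ratio scaling, quantile normalization, fits of only the groups compared, the replicate number as a block, and each library left out in turn. Fits with limma voom on the rebuilt reads and leaving out 3 libraries together were added later. The count-model alternative planned for raw counts was not run since the table holds TPM. Figures and tables were made with R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.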

Results

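RNA sequencing measured transcript levels in MCF7, an estrogen receptor positive human breast cancer cell line, after 24 hours at 20% or 1% oxygen. The cells came from 4 subclones: shNTC carried a non-targeting short hairpin RNA, and the others carried hairpins against HIF-1α, against FACT, or against RNF20 and RNF40. HIF1A encodes the oxygen-regulated subunit of HIF-1, the transcription factor that switches on genes when oxygen is low. SUPT16H and SSRP1 form FACT, a histone chaperone that opens and rebuilds nucleosomes during transcription, and RNF20 with RNF40 form the ligase that attaches ubiquitin to histone H2B. The 24 libraries made 8 groups of subclone and oxygen level, each with 3 biological replicates per the labels. Read numbers rebuilt from the deposited values, which are lower bounds, ran from 23.2 M to 39.6 M per library, with a median of 31.6 M. Levels are given in TPM as mean ± SD (n = 3 libraries), and changes as log2 fold changes ± SE of log2(TPM + 1), which understates the change of low genes. Each knockdown was 1 subclone, so what a subclone brought with it could not be separated from what its hairpin did.

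The hairpin targets were lower in the subclones named for them at both oxygen levels. HIF1A (chromosome 14, 61695513 to 61748259 in GRCh38) stood at 48.4 ± 2.46 TPM in shNTC and 9.91 ± 0.886 TPM in shHIF-1α at 20% O2, and at 48.1 ± 3.4 and 11.2 ± 1.20 TPM at 1% O2. SUPT16H (chromosome 14, 21351472 to 21384266) fell from 154 ± 6.55 TPM in shNTC to 12.7 ± 0.610 TPM in shFACT at 20% O2, and from 163 ± 4.69 to 10.9 ± 0.667 TPM at 1% O2. SSRP1 (chromosome 11, 57325985 to 57335877) fell from 209 ± 3.14 to 23.2 ± 0.793 TPM at 20% O2 and from 227 ± 2.55 to 20.4 ± 0.868 TPM at 1% O2. RNF20 (chromosome 9, 101533851 to 101563344) fell from 44.3 ± 2.45 to 11.6 ± 0.121 TPM in shRNF20/40 at 20% O2 and from 59.1 ± 2.29 to 10.7 ± 0.730 TPM at 1% O2. RNF40 (chromosome 16, 30761745 to 30776307) fell less, from 153 ± 7.88 to 72.9 ± 0.826 TPM at 20% O2 and from 138 ± 1.72 to 62.9 ± 7.68 TPM at 1% O2. The adjusted p for a target in its own subclone lay between 2.2e-22 for SSRP1 at 1% O2 and 7.8e-11 for RNF40 at 20% O2. Targets also moved outside their own subclone. RNF20 was lower in shFACT, at 25.8 ± 2.06 TPM at 20% O2 (log2 change -0.76 ± 0.08, adjusted p = 1e-07) and 28.4 ± 3.48 TPM at 1% O2 (-1.04 ± 0.08, adjusted p = 1.1e-09). HIF1A was higher in shFACT, by 0.78 ± 0.11 at 20% O2 (adjusted p = 2.6e-06) and 0.61 ± 0.11 at 1% O2 (adjusted p = 5.1e-05). SSRP1 was lower in shRNF20/40, by -0.49 ± 0.04 at 20% O2 (adjusted p = 1.2e-09) and -0.56 ± 0.04 at 1% O2 (adjusted p = 1.4e-10).

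**Figure D1:**
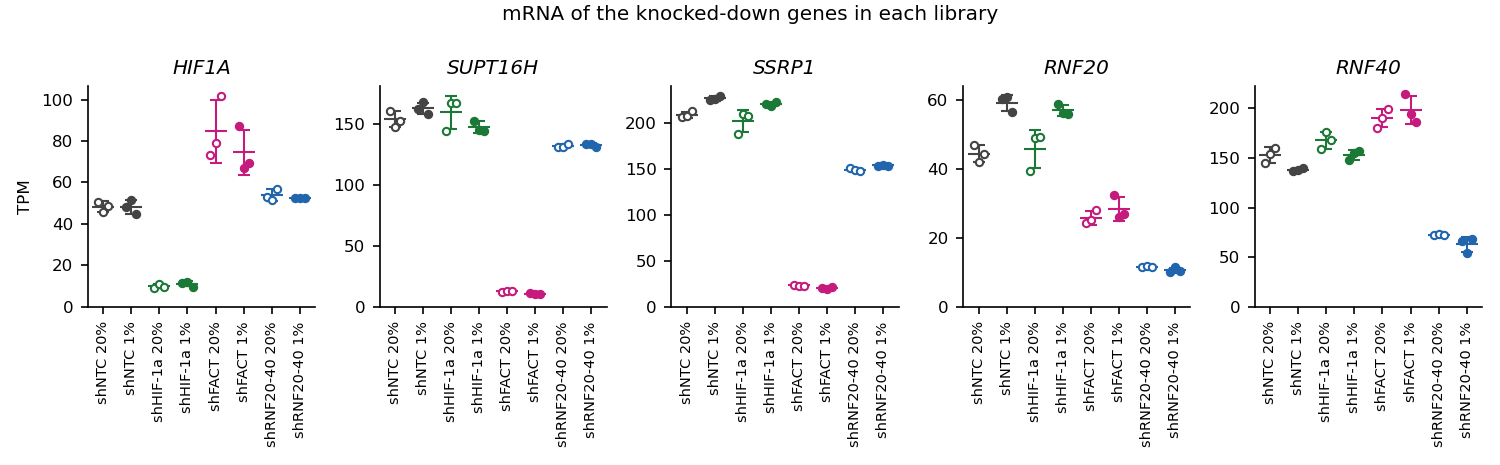
TPM of HIF1A, SUPT16H, SSRP1, RNF20 and RNF40 in each library (open points 20% O2, filled points 1% O2), with the mean and SD of the 3 libraries per group. Each target lies lowest in the subclone whose hairpin was made against it, and RNF20 lies lower in shFACT than in shNTC.

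The first comparison asked which genes answered 24 hours of low oxygen in control cells. In shNTC, 1% O2 raised nearly all genes of glucose uptake and glycolysis and most classical HIF targets and collagen-modifying enzymes, while transcripts of the mitochondrial genome and many replication-dependent histone genes fell. CA9, a carbonic anhydrase that exports acid, was listed at 0 in all 3 shNTC libraries at 20% O2 and reached 49.97 ± 1.84 TPM at 1% O2. NDRG1, a stress-responsive growth regulator, rose from 6.61 ± 0.259 to 292 ± 23.4 TPM (log2 change 5.26 ± 0.07, adjusted p = 1.5e-20). PPFIA4, a liprin scaffold protein, rose from 1.77 ± 0.283 to 149 ± 7.46 TPM (5.76 ± 0.11, adjusted p = 6.8e-19).

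All 10 sentinel hypoxia genes were called higher (camera adjusted p = 9.8e-16; 10 higher when adjusted over the list alone). They included PDK1, a kinase that inhibits pyruvate dehydrogenase (4.10 ± 0.09), BNIP3, a mitophagy receptor (3.72 ± 0.06), ADM, the vasodilator adrenomedullin (4.21 ± 0.13), VEGFA, the main angiogenic factor (2.58 ± 0.10), and SLC2A1, the glucose transporter GLUT1 (0.99 ± 0.05). Of 21 glucose uptake and glycolysis genes, 20 were called higher, 0 lower and 1 was not called (camera adjusted p = 1.2e-24; 20 higher when adjusted over the list alone), led by ALDOC, PGK1, PFKFB4 and LDHA at 3.66, 2.90, 4.18 and 2.54. Of 26 other classical HIF targets, 24 were called higher and 1 lower (camera adjusted p = 3e-25; 24 and 1 when adjusted over the list alone). DDIT4, an inhibitor of mTORC1, rose from 131 ± 1.22 to 2279 ± 25.3 TPM. Of 9 collagen-modifying enzymes, 6 were called higher and 1 lower (camera adjusted p = 6.5e-05; 6 and 2 when adjusted over the list alone), among them the lysyl oxidases LOX (4.72 ± 0.12) and LOXL2 (4.24 ± 0.10) and the prolyl hydroxylase P4HA2 (3.6 ± 0.07).

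Of the 13 protein-coding genes of the mitochondrial genome, 11 were called lower and 2 were not called (camera adjusted p = 1.8e-12; 1 higher and 11 lower when adjusted over the list alone). The list had an adjusted p = 0.06 with an estimated correlation. MT-CO3, a subunit of cytochrome c oxidase, fell by 1.96 and MT-CYB, of complex III, by 1.53. Mitochondrial transcripts made up 19.8% of TPM in shNTC at 20% O2 and 11.7% at 1% O2. Among nuclear-encoded respiratory chain genes 3 of 33 were called higher and 7 lower (camera adjusted p = 0.081, but 0.025 without shNTC 20% O2 replicate 3, 0.028 without shNTC 1% O2 replicate 3 and 0.0043 with median-ratio scaling). Of 46 replication-dependent histone genes, 22 were called lower, 0 higher and 24 were not called (camera adjusted p = 8.4e-10; 22 lower when adjusted over the list alone), with H2AC6 down by -1.88 ± 0.08. The estrogen response list split, with 7 of 23 called higher, such as CCND1, the cyclin D1 gene (1.42 ± 0.04), and 12 lower, such as ELOVL2, a fatty acid elongase (-2.08 ± 0.10; camera adjusted p = 0.0056, and adjusted p = 0.53 with an estimated correlation). Cholesterol synthesis leaned upward, with 15 of 24 genes called higher and 4 lower (camera adjusted p = 0.009; 16 and 5 when adjusted over the list alone; adjusted p = 0.58 with an estimated correlation). Across all 20687 genes tested with limma, 6229 were called higher and 2833 lower at 1% O2, of which 2237 and 771 changed at least 1.5-fold. The excess of higher calls depended on scaling, with 4702 and 4463 under median-ratio scaling, 4280 and 4624 under quantile normalization and 4658 and 4762 with voom.

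The next comparisons asked what loss of HIF-1α did at each oxygen level. At 20% O2 most sentinel hypoxia genes were not called. The largest rise was in KRT16, a stress keratin of squamous epithelium, which rose from 0.118 ± 0.0319 to 21.7 ± 2.19 TPM (log2 change 4.34 ± 0.11, adjusted p = 2.6e-15). KRT1, an epidermal keratin, the calcium-binding alarmins S100A8 and S100A9, FATE1, a testis-expressed gene, and AREG, an EGF receptor ligand, rose as well, by 3.68, 3.28, 3.4, 3.30 and 1.82. SPRR1A and SPRR1B, cornified envelope proteins, were listed at 0 in shNTC and were called higher in shHIF-1α. At 1% O2 the hypoxia program was the main loss: CA9 stood at 1.66 ± 0.441 TPM against 49.97 ± 1.84 TPM in shNTC (-4.28 ± 0.11, adjusted p = 5.9e-16). PGK1, a glycolytic kinase, stood at 282 ± 1.08 against 1469 ± 47.4 TPM (-2.37 ± 0.05, adjusted p = 3.1e-17).

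At 20% O2, 1 sentinel gene was called higher (EGLN3, 0.38), 1 lower (ANKRD37, -0.90) and 8 were not called (camera adjusted p = 0.99). EGLN3 was no longer called at a pseudocount of 5 (0.12, adjusted p = 0.18), when only those groups were fitted (adjusted p = 0.15), without shNTC replicate 3 (adjusted p = 0.094) or without shHIF-1α replicate 2 (adjusted p = 0.09). Of 27 p53 targets, 13 were called higher and 0 lower (camera adjusted p = 1.7e-12; 19 higher when adjusted over the list alone), led by the cell cycle inhibitor CDKN1A (1.21 ± 0.05) and the stress cytokine GDF15 (1.11 ± 0.05). Interferon response genes were slightly higher, with 16 of 32 called higher and 1 lower (median 0.35, camera adjusted p = 9e-08; 17 and 3 when adjusted over the list alone; adjusted p = 0.3 with an estimated correlation). Of 8 basal and mesenchymal markers, 4 were called higher and 0 lower (camera adjusted p = 1.8e-06; 4 higher when adjusted over the list alone), including KRT17, a basal keratin, and TP63, the basal lineage p53 relative, at 1.63 and 1.16. At 1% O2 all 10 sentinel genes were called lower (median -2.05, camera adjusted p = 1.6e-21), as were 19 of 21 glycolysis genes (camera adjusted p = 1.1e-32; 1 higher and 19 lower when adjusted over the list alone). So were 24 of 26 other classical HIF targets (camera adjusted p = 2.8e-32; 24 lower when adjusted over the list alone) and 6 of 9 collagen-modifying enzymes (camera adjusted p = 5e-08; 6 lower when adjusted over the list alone). DDIT4 was the exception among strong HIF targets, at 2361 ± 37.4 TPM against 2279 ± 25.3 TPM; it was chosen after its values were seen.

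At 1% O2, 28 of 30 DNA replication genes were called lower with shHIF-1α and 0 higher (median -0.40, camera adjusted p = 1.6e-17; 29 lower when adjusted over the list alone). DHFR, which makes tetrahydrofolate for thymidylate synthesis, was lower by -0.66 ± 0.06 and the helicase subunit MCM2 by -0.51 ± 0.06. Cholesterol synthesis rose, with 22 of 24 genes called higher (camera adjusted p = 1.1e-16; 22 when adjusted over the list alone), such as MVD of the mevalonate pathway (1.23 ± 0.09). So did 18 of 22 ATF4 and unfolded protein response genes (3 lower, camera adjusted p = 4.7e-11; 18 and 3 when adjusted over the list alone). TRIB3, a pseudokinase that restrains ATF4, was higher by 1.10 ± 0.05, and CHAC1, which degrades glutathione, by 2.21 ± 0.14. Among p53 targets 19 of 27 were called higher and 2 lower (camera adjusted p = 6.1e-11; 20 and 2 when adjusted over the list alone). In all, shHIF-1α differed from shNTC in 1056 genes called higher and 705 lower at 20% O2, and in 2853 and 2637 at 1% O2. The 1761 calls at 20% O2 became 1088 without shNTC replicate 2, 1157 without shNTC replicate 3 and 1163 without shHIF-1α replicate 2. They became 2903 without 3 of the libraries that stood apart from their replicates, and 967 when only those groups were fitted. In shHIF-1α at 20% O2, replicate 1 had 23.5% of its TPM in mitochondrial transcripts against a group mean of 20.0 ± 2.99%.

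The comparisons of shFACT with shNTC asked what loss of the histone chaperone did apart from hypoxia. The change was far wider than with shHIF-1α: interferon response genes, p53 targets and inflammatory genes rose, and DNA replication and mitosis genes fell. IFI6, an interferon-induced mitochondrial protein, rose from 13.1 ± 0.799 to 6272 ± 715 TPM at 20% O2 (log2 change 8.79 ± 0.12, adjusted p = 1.3e-21), and IFIT3, an antiviral RNA-binding adaptor, from 0.509 ± 0.253 to 1261 ± 43.7 TPM (9.72 ± 0.12, adjusted p = 3.1e-22). The chemokine CCL5 rose from 0.147 ± 0.142 to 980 ± 135 TPM. CDKN1A rose from 91.8 ± 1.65 to 2143 ± 59.5 TPM (4.53 ± 0.05, adjusted p = 2.4e-23), and MKI67, the proliferation antigen Ki-67, fell from 217 ± 13.9 to 19.0 ± 2.95 TPM (-3.45 ± 0.10, adjusted p = 1.5e-16).

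At 20% O2 all 32 interferon response genes were called higher with shFACT (median 5.48, camera adjusted p = 5e-23), as were all 27 p53 targets (median 2.20, camera adjusted p = 6.9e-14) and all 17 NF-kB and inflammatory genes (median 2.74, camera adjusted p = 1e-09). These counts were the same when adjusted over the list alone. All 30 DNA replication genes (median -1.93, camera adjusted p = 8e-24) and all 25 mitosis genes (median -2.53, camera adjusted p = 2e-23) were called lower, again with the same counts when adjusted over the list alone. MCM5 of the replicative helicase fell by 2.19, FOXM1, which drives mitotic genes, by 3.16, and PLK1, a mitotic kinase, by 3.00. Histone genes went the other way, with 29 of 46 called higher and 4 lower (camera adjusted p = 0.009; 31 and 5 when adjusted over the list alone; adjusted p = 0.35 with an estimated correlation). The histone gene H4C8 rose from 3.83 ± 0.180 to 116 ± 2.30 TPM. Of 8 basal and mesenchymal markers, 7 were called higher (camera adjusted p = 0.0012; 7 when adjusted over the list alone), with KRT17 at 246 ± 26.1 TPM against 0.287 ± 0.0704 TPM in shNTC. Leukocyte markers summed to 3.58 ± 0.60 TPM in shFACT and 0.98 ± 0.10 TPM in shNTC at 20% O2.

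Some HIF pathway components changed with shFACT at 20% O2, and that list as a whole is not described here. EPAS1 (chromosome 2, 46293667 to 46386703), which encodes HIF-2α, rose from 0.293 ± 0.0574 to 33.6 ± 5.63 TPM (4.73 ± 0.11, adjusted p = 4.6e-18), and CITED2, which competes with HIF-1α for its coactivator, rose by 2.80 ± 0.06. ADM stood at 47.9 ± 4.52 TPM against 0.841 ± 0.1 TPM in shNTC (4.73 ± 0.13, adjusted p = 3.9e-17) and VEGFA at 48.9 ± 5.61 against 16.8 ± 0.605 TPM (1.48 ± 0.10, adjusted p = 6e-11). LDHA and SLC2A1 were lower, by -1.86 ± 0.04 and -1.12 ± 0.05. Of 21 glycolysis genes 13 were called lower and 3 higher (camera adjusted p = 0.00022; 13 and 3 when adjusted over the list alone; adjusted p = 0.31 with an estimated correlation). At 1% O2, 20 of 21 glycolysis genes were called lower and 0 higher (median -1.03, camera adjusted p = 2.1e-11; 20 lower when adjusted over the list alone). Of the sentinel genes 8 of 10 were lower and 2 higher (camera adjusted p = 0.00089; adjusted p = 0.17 with an estimated correlation). Interferon genes (32 of 32 higher, median 5.27, camera adjusted p = 2.1e-24), DNA replication genes (30 of 30 lower, median -1.91, camera adjusted p = 1.3e-20) and mitosis genes (25 of 25 lower, median -2.61, camera adjusted p = 1.3e-20) moved the same way against shNTC at 1% O2 as at 20% O2. In total 8499 genes were called higher and 5311 lower at 20% O2 (6435 and 7550 under quantile normalization), and 7433 and 6524 at 1% O2 (6682 and 7360).

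The comparisons of shRNF20/40 with shNTC asked the same of the H2B ubiquitin ligase. The direction of the main gene groups was that of shFACT and the size was smaller: interferon genes rose and replication and mitosis genes fell. IFI6 rose from 13.1 ± 0.799 to 1997 ± 234 TPM at 20% O2 (log2 change 7.14 ± 0.12, adjusted p = 9.5e-20), and S100P, a calcium-binding protein, from 15.3 ± 2.16 to 2306 ± 226 TPM (7.15 ± 0.11, adjusted p = 4.6e-20). The metallothioneins MT2A, MT1X and MT1F, which bind zinc and copper, were lower at 20% O2, by -2.73, -2.62 and -2.77, and STC1, the secreted hormone stanniocalcin, by -2.65. At 1% O2 the largest falls were in LOX (-4.46 ± 0.12, adjusted p = 5.5e-17) and LOXL2 (-3.81 ± 0.10, adjusted p = 1e-16), at 0.712 ± 0.160 and 8.38 ± 1.07 TPM against 36.5 ± 3.21 and 130 ± 5.66 TPM in shNTC.

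All 32 interferon response genes were called higher with shRNF20/40 at 20% O2 (median 3.59, camera adjusted p = 7.8e-27) and at 1% O2 (median 3.96, camera adjusted p = 4.1e-30). All 30 DNA replication genes were called lower at 20% O2 (median -0.99, camera adjusted p = 4.5e-17) and at 1% O2 (median -1.06, camera adjusted p = 6e-15). So were all 25 mitosis genes at 20% O2 (median -1.07, camera adjusted p = 3.7e-16) and at 1% O2 (median -1.13, camera adjusted p = 1.4e-13). Of 17 NF-kB and inflammatory genes, 13 were called higher at 20% O2 (camera adjusted p = 3.4e-06; 13 when adjusted over the list alone), with RELB, a subunit of the noncanonical pathway, at 53.8 ± 2.46 against 2.08 ± 0.0893 TPM. Of 27 p53 targets, 24 were called higher and 3 lower at 20% O2 (camera adjusted p = 3.4e-08; 24 and 3 when adjusted over the list alone; adjusted p = 0.061 with an estimated correlation), with GDF15 up by 4.28 ± 0.05. EPAS1 rose here too, from 0.293 ± 0.0574 to 13.2 ± 0.984 TPM at 20% O2 (3.46 ± 0.11, adjusted p = 1.8e-15). At 1% O2, 19 of 21 glycolysis genes were called lower and 1 higher (median -0.85, camera adjusted p = 5.5e-08; 19 and 1 when adjusted over the list alone; adjusted p = 0.083 with an estimated correlation). Of 9 collagen-modifying enzymes, 8 were lower and 1 higher (camera adjusted p = 0.00062; adjusted p = 0.073 with an estimated correlation). Leukocyte markers summed to 1.91 ± 0.36 TPM at 20% O2. Genes called numbered 6145 higher and 5794 lower at 20% O2, and 5200 and 7250 at 1% O2 (6441 and 6258 under median-ratio scaling).

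**Figure D2:**
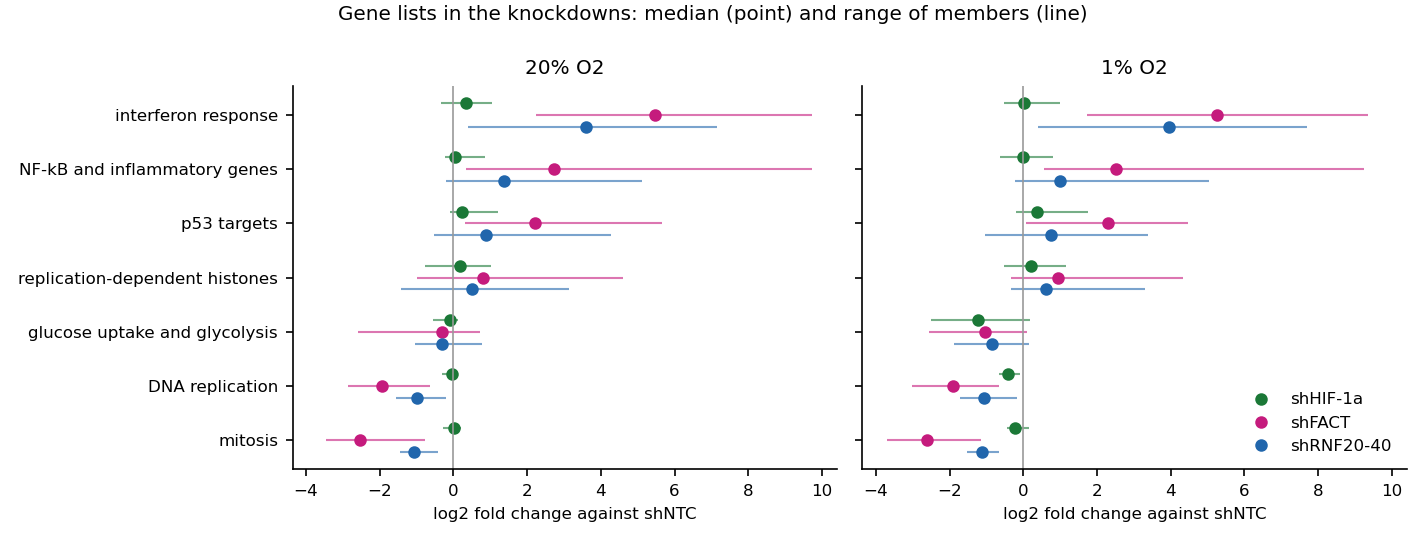
Median log2 fold change against shNTC (points) and range over the list's genes (lines) for 7 gene lists in each knockdown at 20% and 1% O2. The interferon list has medians of 5.48 and 3.59 with shFACT and shRNF20/40 at 20% O2 and of 0.35 with shHIF-1α.

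The central question was how far each knockdown altered the answer to 1% O2. Of the 10 sentinel hypoxia genes, 10 were called higher at 1% O2 in shNTC, 9 in shHIF-1α, 9 in shFACT and 10 in shRNF20/40. NDRG1, which rose by 5.26 in shNTC, rose by 2.76 in shHIF-1α, 2.56 in shFACT and 2.96 in shRNF20/40, each with an SE of 0.07. ADM rose by 4.21 in shNTC and 1.25 in shHIF-1α; in shFACT it stood at 47.9 ± 4.52 TPM at 20% O2 and 44.0 ± 2.46 TPM at 1% O2 (-0.12 ± 0.13, adjusted p = 0.63). SLC2A1 differed by knockdown: it rose by 0.99 ± 0.05 in shNTC and 1.09 ± 0.05 in shFACT, by 0.59 ± 0.05 in shRNF20/40, and was not called in shHIF-1α (-0.11 ± 0.05, adjusted p = 0.11), where it was called lower with median-ratio scaling (-0.24, adjusted p = 8.9e-05), quantile normalization (-0.18, adjusted p = 0.0058), voom (-0.22, adjusted p = 0.00013) and without the 3 outlying libraries (-0.14, adjusted p = 0.049). The SLC2A1 interaction with shFACT was not called, but lay above 0 with median-ratio scaling (0.22, adjusted p = 0.0052) and voom (0.23, adjusted p = 0.0051).

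**Figure D3:**
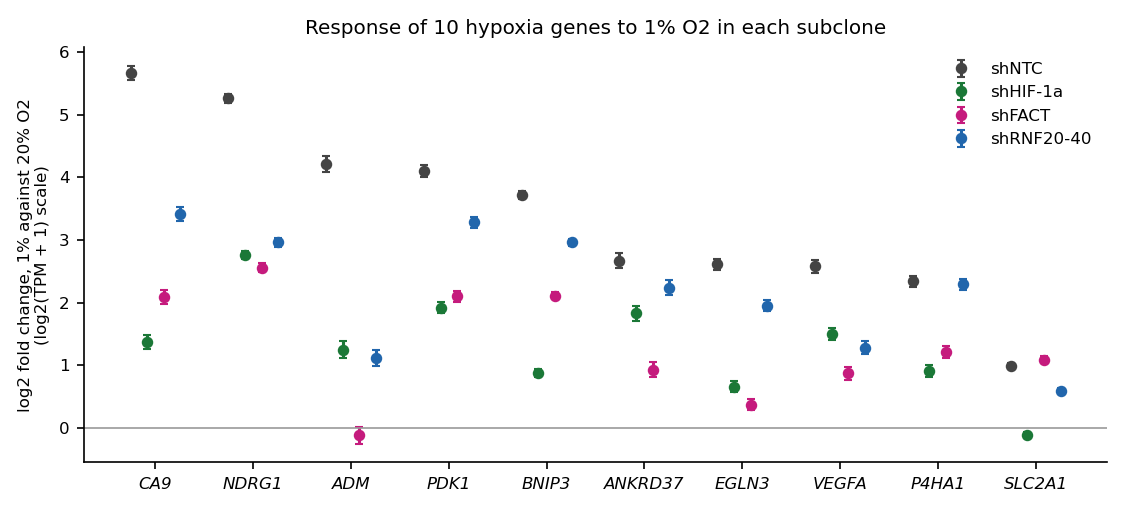
Log2 fold change ± SE between 1% and 20% O2 of the 10 sentinel hypoxia genes in each subclone, on the log2(TPM + 1) scale. BNIP3 changes by 3.72 in shNTC, 0.88 in shHIF-1α, 2.11 in shFACT and 2.96 in shRNF20/40; CA9 was listed at 0 in shNTC at 20% O2, so the height of its points depends on the added 1 TPM.

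Loss of HIF-1α lessened the response of the HIF program across its branches. The interaction of knockdown and oxygen was called below 0 for 10 of 10 sentinel genes (camera adjusted p = 5e-24), for 19 of 21 glycolysis genes (camera adjusted p = 4.4e-35; 1 above and 19 below 0 when adjusted over the list alone). It was also below 0 for 25 of 26 other classical HIF targets (camera adjusted p = 4.3e-42; 25 when adjusted over the list alone) and for 6 of 9 collagen-modifying enzymes (1 above 0, camera adjusted p = 6e-08). BNIP3 differed by -2.84 ± 0.09 (adjusted p = 1.2e-13), PGK1 by -2.36 ± 0.07 (adjusted p = 2.2e-14), LOX by -3.65 ± 0.16 and TMEM45A, a membrane protein, by -3.68 ± 0.14. The response of 17 of 24 cholesterol synthesis genes was called larger than in shNTC (camera adjusted p = 1.8e-14; 18 when adjusted over the list alone), with MVD at 1.29 ± 0.13. That of 14 of 22 ATF4 and unfolded protein response genes was larger too (2 smaller, camera adjusted p = 1.5e-06; 14 and 3 when adjusted over the list alone; adjusted p = 0.074 with an estimated correlation). NUPR1, a stress-induced chromatin protein, went from 4.57 ± 0.0855 to 24.0 ± 0.865 TPM in shHIF-1α and from 7.65 ± 0.532 to 7.84 ± 1.33 TPM in shNTC. Interactions were called above 0 for 1658 genes and below 0 for 1787.

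With shFACT lessened responses also appeared outside the HIF lists. Interactions were called below 0 for 9 of 10 sentinel genes (camera adjusted p = 9.2e-12) and for 24 of 26 other classical HIF targets (1 above 0, camera adjusted p = 1.2e-22; 24 and 1 when adjusted over the list alone). The matricellular gene CCN5 differed by -3.99 ± 0.14, LOX by -3.85 ± 0.16, DPYSL4, a dihydropyrimidinase-like protein, by -3.88 ± 0.14 and SPRY1, a feedback inhibitor of growth factor signalling, by -3.22 ± 0.14. Immediate early and heat shock genes split, with 9 of 17 above 0 and 6 below (median 0.18 and mean -0.23, camera adjusted p = 0.39; 9 and 7 when adjusted over the list alone). FOS and JUN, which form the transcription factor AP-1, were among those below, at -2.27 ± 0.12 and -1.87 ± 0.13. Glycolysis was affected less: 14 of 21 genes were called below 0 and 2 above (median -0.51, camera adjusted p = 2.2e-07; 14 and 3 when adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). LDHA rose by 2.88 ± 0.04 in shFACT and 2.54 ± 0.04 in shNTC, with LDHA pseudogenes able to take some of its reads. As a list, mitochondrially encoded genes fell less at 1% O2 than in shNTC (camera adjusted p = 8.6e-11, and adjusted p = 0.1 with an estimated correlation). Of their 13 interactions 10 were called above 0, and 10 above and 1 below 0 when adjusted over the list alone. MT-CO3 differed by 1.68 ± 0.12, and mitochondrial transcripts went from 12.8% to 10.9% of TPM. Cholesterol synthesis genes lost their rise, with 17 of 24 below 0 and 2 above (camera adjusted p = 6.2e-05; 17 and 3 when adjusted over the list alone; adjusted p = 0.22 with an estimated correlation). INSIG1, the sterol-sensing retention protein, differed by -1.32 ± 0.09. Interactions were called above 0 for 2038 genes and below 0 for 4556. The excess below 0 depended on scaling, with 3235 and 3523 under median-ratio scaling, 3410 and 2935 under quantile normalization and 3407 and 3240 with voom. The response within shFACT, 1506 genes called higher and 1381 lower at 1% O2, fell from 2887 to 680 calls when only those groups were fitted.

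With shRNF20/40 most sentinel genes responded less than in shNTC, and LOX, ANGPTL4 and ADM lost most of their response. Interactions were called below 0 for 8 of 10 sentinel genes (camera adjusted p = 1.6e-08; 9 when adjusted over the list alone; adjusted p = 0.054 with an estimated correlation). They were below 0 for 21 of 26 other classical HIF targets (1 above 0, camera adjusted p = 9e-20; 23 and 1 when adjusted over the list alone; adjusted p = 0.054 with an estimated correlation) and for 15 of 21 glycolysis genes (1 above 0, camera adjusted p = 1.6e-08; 15 and 1 when adjusted over the list alone; adjusted p = 0.1 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase, rose by 2.29 ± 0.09 against 2.34 ± 0.09 in shNTC, an interaction that was not called (-0.05 ± 0.13, adjusted p = 0.82). LOX differed by -4.19 ± 0.16, ANGPTL4, a secreted inhibitor of lipoprotein lipase, by -3.35 ± 0.10 and ADM by -3.09 ± 0.18. Cholesterol synthesis genes lost their rise, with 19 of 24 below 0 and 1 above (camera adjusted p = 4.9e-10; 19 and 1 when adjusted over the list alone; adjusted p = 0.074 with an estimated correlation). Responses above those of shNTC included UCA1, a long noncoding RNA (2.38 ± 0.19), HES1, a Notch target (1.80 ± 0.09), and MT1X (2.17 ± 0.16). Interactions were called above 0 for 1542 genes and below 0 for 3765, and for 2771 and 2929 under median-ratio scaling, 2717 and 2577 under quantile normalization and 2672 and 3022 with voom.

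Measured over whole lists, the mean log2 response of the sentinel genes, 3.42 in shNTC, was 37.9% of that size in shHIF-1α, 38.6% in shFACT and 64.6% in shRNF20/40. For glucose uptake and glycolysis genes the shares were 40.9%, 64.1% and 70.6% of a mean of 2.01, and for collagen-modifying enzymes 34.9%, 38.2% and 46.8% of a mean of 1.96. Among the 2237 genes called at least 1.5-fold higher at 1% O2 in shNTC, induction was called reduced for 838 genes (37.5%) with shHIF-1α, 1841 (82.3%) with shFACT and 1707 (76.3%) with shRNF20/40, and called enlarged for 47, 8 and 3. The median ratio of the response to that in shNTC was 0.57, 0.13 and 0.2, and that of shFACT ran from 0.07 to 0.19 with single libraries left out. Simulated knockdowns without any effect gave a median ratio of 0.949 from the selection of these genes alone. They gave 0% reduced, but without any true effect hardly any interaction can be called, so that share does not measure the selection. Genes chosen and measured on separate shNTC replicates gave 19.5%, 51.3% and 43.4% reduced, with 1 shNTC replicate per oxygen level left for the response; the median ratios there were 0.57 to 0.66, 0.13 to 0.14 and 0.2 to 0.23. Induction was called reduced with all 3 knockdowns for 707 genes. Independent calls would give 526.3, a value that leaves out the shared shNTC libraries, so part of that excess may come from the shared controls. A further 867 were called reduced with shFACT and shRNF20/40 and not with shHIF-1α, and 216 with none of the 3. Of the genes reduced with shHIF-1α, 90.7% were also reduced with shFACT and 88.1% with shRNF20/40; of the genes not reduced with it, 77.3% and 69.3% were, a difference to which the shared controls may also add. A reduced response can come from either oxygen level. With shHIF-1α, 678 of the 838 genes were called lower than shNTC at 1% O2 alone, 52 higher at 20% O2 alone and 70 both. With shFACT 895 were lower at 1% O2 alone, 654 higher at 20% O2 alone and 284 both, and with shRNF20/40 the numbers were 940, 505 and 253. Of the 771 genes at least 1.5-fold lower at 1% O2 in shNTC, the fall was called lessened for 296 with shHIF-1α, 592 with shFACT and 540 with shRNF20/40.

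**Figure D4:**
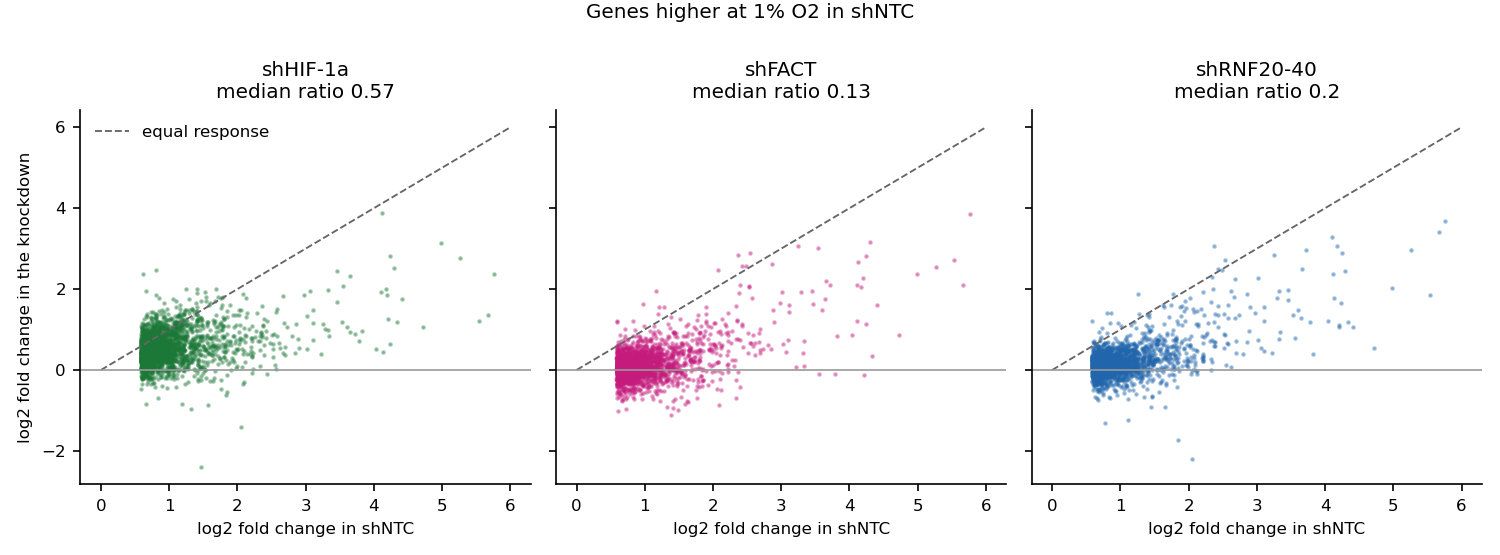
Log2 fold change between 1% and 20% O2 in each knockdown (vertical) against that in shNTC (horizontal) for the 2237 genes called at least 1.5-fold higher in shNTC, 1 point per gene, with a dashed line where the responses are equal. The points lie closest to 0 with shFACT and shRNF20/40, with median ratios of 0.13 and 0.2 against 0.57 with shHIF-1α.

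The interactions of shFACT and shRNF20/40 overlapped most. They shared 2838 genes below 0, against 829.2 for independent lists, and 1202 above 0, against 151.9, while 11 genes went in opposite directions. Across genes, which are not independent replicates, the covariance of these interactions was 0.178, which exceeded that of simulated unchanged knockdowns with the same controls by 0.134. The Pearson correlation was 0.72, against 0.498 in the simulation. The covariance ran from 0.076 at a pseudocount of 5 to 0.495 at a pseudocount of 0.1, settings at which the simulation was not repeated. The excess was 0.065 for shHIF-1α with shFACT, which shared 1102 genes below 0 (393.6 if independent), and 0.051 for shHIF-1α with shRNF20/40, which shared 988 (325.2 if independent). At those pseudocounts the covariances of these pairs were 0.045 and 0.363, and 0.037 and 0.334. Their correlations were 0.48 and 0.45, and those in the simulation 0.504 and 0.502. The simulated correlations are set by the sharing of controls where there is no effect. They are therefore no scale for these correlations or for the 0.72, and no conclusion was drawn from them. The simulated knockdowns shared 0 genes. With 3 shNTC libraries per group, 2 comparisons could not each be given 2 of their own, so the controls were not divided. The numbers expected of independent lists do not allow for the shared controls, and the simulated covariances do. The simulated count of 0 shared genes does not, since knockdowns without any effect leave hardly any called genes to share. How far the shared controls raised the counts of shared genes was not measured.

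The authors deposited 3 gene lists chosen on these same libraries, so their overlap here is not independent evidence. Of the authors' HIF-1-dependent hypoxia-induced genes, 1164 could be tested and 1156 were called higher at 1% O2 in shNTC; their response was lessened for 669 (57.5%) with shHIF-1α, 979 (84.1%) with shFACT and 924 (79.4%) with shRNF20/40. Of the 701 genes on the longer hypoxia-induced list that were tested and lay outside the HIF-1-dependent one, the response was lessened for 43, 617 and 576. Of the 2237 induced genes found here, 1634 were on the authors' hypoxia-induced list. On the authors' hypoxia-repressed list, 1439 genes were tested and 1355 were called lower.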

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

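The test of the gene-length trend on reduced induction was chosen before its result was seen. The interactions with shNTC, and median-ratio scaling of the counts of reduced induction, were planned before the data were examined. The other tests in this part, and the other rules for weighing explanations, were chosen after the results they concern were seen.

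Responses to 1% O2 that differed between subclones are set out here, each by a test of the difference itself with limma. In single genes, the response differed from that in shNTC for 3445 genes in shHIF-1α, 6594 in shFACT and 5307 in shRNF20/40. Among gene lists called in opposite directions, cholesterol synthesis stood out. The median log2 change of its 24 genes at 1% O2 was 0.36 in shNTC (15 called higher and 4 lower, and the list not called with an estimated correlation, adjusted p = 0.58), 0.82 in shHIF-1α, -0.13 in shFACT and -0.26 in shRNF20/40. MVD, which makes isopentenyl diphosphate, went from 129 ± 7.40 to 205 ± 10.2 TPM in shNTC, from 124 ± 4.06 to 483 ± 27.5 TPM in shHIF-1α and from 132 ± 4.44 to 81.7 ± 14.7 TPM in shRNF20/40. The median of the differences from shNTC was -0.46 in shFACT (camera adjusted p = 6.2e-05, and 0.22 with an estimated correlation) and -0.63 in shRNF20/40 (adjusted p = 4.9e-10, and 0.074 with an estimated correlation). Against shHIF-1α it was -0.95 in shFACT (adjusted p = 2.3e-16, and 0.027 with an estimated correlation) and -1.18 in shRNF20/40 (adjusted p = 3.1e-21, and 0.016 with an estimated correlation).

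Cell cycle, p53 and interferon lists were also called in opposite directions between pairs of knockdowns, mostly by differences not called with an estimated correlation. Of 30 DNA replication genes, 13 were called lower and 1 higher at 1% O2 in shHIF-1α (median -0.12), and 0 lower and 12 higher in shFACT (0.18), with a median difference of 0.28 (adjusted p = 1.6e-11, and 0.063 with an estimated correlation). Mitosis genes differed by 0.21 between shFACT and shHIF-1α (adjusted p = 1.3e-06, and 0.11 with an estimated correlation) and by 0.23 between shRNF20/40 and shHIF-1α (adjusted p = 1.6e-05, and 0.18 with an estimated correlation). Of 27 p53 targets, 14 were called higher and 4 lower at 1% O2 in shHIF-1α (median 0.19), and 1 higher and 7 lower in shFACT (-0.13), with a median difference of -0.35 (adjusted p = 3.3e-05, and 0.14 with an estimated correlation). CDKN1A went from 213 ± 11.9 to 448 ± 6.24 TPM in shHIF-1α and from 2143 ± 59.5 to 1786 ± 118 TPM in shFACT, a fall not called when only those groups were fitted (adjusted p = 0.072). Of 32 interferon response genes, 11 were called higher and 0 lower in shRNF20/40 (median 0.19), 1 higher and 17 lower in shHIF-1α (-0.25), and 0 higher and 12 lower in shFACT (-0.25). The median differences were 0.53 between shRNF20/40 and shHIF-1α (adjusted p = 3e-10, and 0.088 with an estimated correlation) and 0.5 between shRNF20/40 and shFACT (adjusted p = 5e-19, and 0.027 with an estimated correlation). OAS1, an antiviral RNA sensor, went from 177 ± 5.08 to 158 ± 9.44 TPM in shFACT, a change called with voom on the rebuilt reads alone (adjusted p = 0.037), and from 80.4 ± 5.71 to 120 ± 11.7 TPM in shRNF20/40.

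The first pattern weighed was reduced induction of most hypoxia-induced genes with shFACT and shRNF20/40. The tables argue against 3 explanations as the whole cause. With median-ratio scaling the share reduced was at least 77.2% in both subclones, and after removal of each library's trend with gene length at least 77.6%. That removal left 1599 induced genes in place of 2237, so the share covers a smaller set. The median interaction with shFACT was -0.11 in the shortest genes and -0.26 in the longest before the removal, and 0.08 and -0.01 after it. With shRNF20/40 it was -0.08 and -0.21 before, and 0.03 and 0.01 after, so the trend was not removed exactly. At least 64% of the genes reduced were called lower than shNTC at 1% O2, so a raised level at 20% O2 alone does not account for those genes. Some of them were also called higher at 20% O2, 284 with shFACT and 253 with shRNF20/40, where both levels can add to the reduction. Another 654 and 505 genes were called higher at 20% O2 alone, and for these a raised level stays open. A candidate explanation is that FACT and H2B ubiquitination serve the induction itself, a hypothesis that came from these same data and was not itself tested. Each knockdown being 1 subclone with a wide change at 20% O2, an effect of the subclone or of that altered state stays open and was not tested.

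The second pattern was the rise of interferon response genes with shFACT and shRNF20/40. Immune cells in the culture are argued against by leukocyte markers that summed to at most 3.84 TPM in the 4 groups, against IFI6 at 6272 ± 715 TPM in shFACT at 20% O2. List medians of at least 3.63 under median-ratio scaling argue against the scaling of the table. A response to carrying any hairpin construct is argued against as the whole cause. By the labels shNTC carried one too, and with shHIF-1α the list's median was 0.35 at 20% O2, where the list was called higher (adjusted p = 0.3 with an estimated correlation), and 0.03 at 1% O2, against at least 3.59 with shFACT and shRNF20/40. This comparison of sizes was set after the medians were seen, in place of an earlier rule that asked whether the list was called higher at both oxygen levels and left the explanation open. The number and make-up of the constructs in each subclone are not stated, and the deposited column names mark all 3 knockdowns with the same unexplained letters, DKD, so an effect of how many constructs a subclone carried stays open. Loss of FACT or of the ligase may release the interferon response, and this stays untested beside the number of constructs and the subclone.

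The third pattern was that glucose uptake and glycolysis genes lost less of their response with shFACT and shRNF20/40 than other induced genes did. Among 10000 random lists of genes matched on the response and level in shNTC, the median interaction lay at the percentile 99.75 or above in both subclones, and after removal of the length trend at 99.25 or above. The matched genes were still lower in level (mean log2 6.52 against 7.93) and in response (1.72 against 2.01), so matching was incomplete. With shHIF-1α the percentile depended on the matching: it was 13.22, or 8.46 with the length trend removed, and 60.02 and 47.82 when each gene was matched to 10 others in place of 40. With shFACT and shRNF20/40 the list lost less than the random genes did, and removing the length trend left that difference in place. Response size and level are not settled, since matching on them was incomplete. The random genes were also drawn independently of one another, so the percentiles are too extreme if the list's genes vary together. Most of the glycolysis genes were nonetheless called lower than shNTC at 1% O2 in both subclones. In shFACT most were also called lower at 20% O2, where a lowered level can leave the fold response in place. A smaller need of these genes for FACT and the ligase therefore cannot be read from the kept response. That explanation stays untested beside the subclone and the lowered level.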

How the results depend on the processing

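Fits with voom on the rebuilt reads, fits without 3 outlying libraries together, the leaving out of single libraries for lists and overlaps, and the other settings for lists and overlaps were chosen after seeing the data. The 9 settings that kept all libraries and the 24 libraries left out in turn were compared with the values reported. Of the total counts of genes called, all but those named here stayed within 1.5 times the reported count.

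Calls of the response in shFACT were 680 when only the groups compared were fitted, and 2064 to 2797 with single libraries left out. With shHIF-1α at 20% O2 the 1761 calls became 967 when only the groups compared were fitted, 2903 without the 3 outlying libraries (shHIF-1α 20% O2 replicate 1, shFACT 20% O2 replicate 3 and shRNF20/40 1% O2 replicate 2), and 1088 to 1932 with single libraries left out, lowest without shNTC 20% O2 replicate 2. By direction, its calls higher went from 1056 to 2135 without the 3 outlying libraries and to as few as 649 with single libraries left out, and its calls lower from 705 to as few as 427. The 1381 calls lower at 1% O2 in shFACT shrank by more than 1.5 times without shFACT 1% O2 replicate 2 or 3. The cause was not tested. Replicate 1 of shFACT at 1% O2 also stood apart from its replicates and was not among the 3 outlying libraries. Its mean chi-square per gene was 12.78 and 16.26 against replicates 2 and 3, which gave 3.46 against each other.

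Genes with reduced induction numbered 982 with shFACT and 949 with shRNF20/40 at a pseudocount of 5 (94% and 90.8% of 1045 induced genes) and 1029 and 1013 with quantile normalization (76.9% and 75.7% of 1338). Among 768 genes induced at least 2-fold they numbered 460, 665 and 644 with shHIF-1α, shFACT and shRNF20/40 (59.9%, 86.6% and 83.9%). With genes selected and measured on separate shNTC replicates the means were 421.7, 1112 and 941 of 2197.3 genes, with fewer control libraries for the response. In the first 3 settings fewer genes counted as induced.

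Of the authors' lists, 1226 hypoxia-induced genes were called with a filter of 5 TPM, which tests fewer genes, and 698 hypoxia-repressed genes were called and changed at least 1.5-fold, a stricter call. Called list tests fell from 175 to 60 with an estimated correlation, which allows for more correlation between a list's genes. Mitochondrially encoded genes with shHIF-1α at 20% O2 (camera adjusted p = 0.95) were called lower without the 3 outlying libraries (0.0025) and without shHIF-1α 20% O2 replicate 1 alone (0.0031), the library with 23.5% of TPM in those genes. No named gene changed sign past the threshold. The fall of CDKN1A at 1% O2 in shFACT was not called when only the groups compared were fitted (-0.26, adjusted p = 0.072), and that of OAS1 was called with voom (-0.18, adjusted p = 0.037). The 29 other values that moved were covariances and median ratios, under other pseudocounts or filters, quantile normalization, selection at 2-fold, or voom. With single libraries left out the median ratio with shFACT ran from 0.07 to 0.19.

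Scaling moved the share of calls that were higher. It was 68.7% for 1% O2 in shNTC, 51.3% with median-ratio scaling, 48.1% with quantile normalization and 49.4% with voom, and for shHIF-1α 69%, 48.2%, 48.6% and 50.6%. For shFACT at 20% O2 it was 61.5%, and 46% with quantile normalization. For the interaction of shFACT it was 30.9%, 47.9%, 53.7% and 51.3%, and of shRNF20/40 29.1%, 48.6%, 51.3% and 46.9%. By direction, calls lower at 1% O2 went from 2833 to between 4463 and 4762 in shNTC and from 2487 to between 4111 and 4308 in shHIF-1α under these 3 settings. Interactions above 0 went from 2038 to between 3235 and 3410 with shFACT and from 1542 to between 2672 and 2771 with shRNF20/40, and those below 0 with shFACT from 4556 to 2935 with quantile normalization. Calls lower with shHIF-1α at 20% O2 went from 705 to 1075 with voom, and its interactions below 0 from 1787 to 2943 without the 3 outlying libraries. The median log2 change of all genes, 0.097 in shNTC, 0.176 with shFACT at 20% O2, -0.132 for its interaction and -0.108 for that of shRNF20/40, shifted by up to -0.224 (shFACT at 20% O2, quantile normalization), so the balance of small changes is relative to these medians.

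With the replicate number as a block, calls were 8842, 7786, 2592 and 3357 for the responses in shNTC, shHIF-1α, shFACT and shRNF20/40; 1534, 13720 and 11805 for shHIF-1α, shFACT and shRNF20/40 at 20% O2; 5186, 13806 and 12278 at 1% O2; and 3202, 6273 and 4993 for the interactions, with 175 list tests called. Same-numbered libraries correlated between -0.178 and 0.063, with 0 of 84 pairs over 0.1, and 4 of 24 libraries correlated best with their own number, so the numbers share only a label.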

Other observations

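All tests of other groupings given here were chosen after the results were seen.

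Interferon genes themselves were transcribed in shFACT. IFNB1, which encodes interferon beta, was listed at 0 in shNTC at both oxygen levels and stood at 43.9 ± 6.79 TPM in shFACT at 20% O2 and 16.9 ± 1.97 TPM at 1% O2, against 2.51 ± 0.188 and 2.53 ± 0.611 TPM in shRNF20/40. IFNL1, a lambda interferon, stood at 124 ± 12.3 and 51.2 ± 3.09 TPM in shFACT; both genes were chosen after their values were seen. Within shFACT, 1% O2 lowered IFNL2 by -1.87 and IFNL3 by -1.41, and 9 of 17 NF-kB and inflammatory genes were called lower and 0 higher (camera adjusted p = 4.3e-08; 12 lower when adjusted over the list alone).

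Estrogen response genes fell at 1% O2 in shHIF-1α, with 17 of 23 called lower and 3 higher (camera adjusted p = 1.5e-11; 19 and 3 when adjusted over the list alone), ELOVL2 at -2.37 among them. In shHIF-1α the interferon list was also lower at 1% O2, with 17 of 32 called lower and 1 higher (camera adjusted p = 5.1e-06; 18 and 1 when adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). Genes at or above 1 TPM numbered 18206 in shFACT and 16119 in shNTC at 20% O2 on average. Luminal markers summed to between 23200 and 32350 TPM over the 24 libraries, and leukocyte markers to between 0.506 and 4.67 TPM.

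Other groupings of the same libraries were compared with the real ones. For 3 libraries against 3 there are 10 groupings, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each comparison. The real count and the highest other were 9062 and 1 for the response in shNTC, 8023 and 1 in shHIF-1α, 2887 and 1908 in shFACT, and 3633 and 1 in shRNF20/40. They were 1761 and 0, 13810 and 2, and 11939 and 1 for shHIF-1α, shFACT and shRNF20/40 at 20% O2, and 5490 and 1, 13957 and 1, and 12450 and 1 at 1% O2. The grouping in shFACT that called 1908 genes joined replicate 1 at 20% O2 with replicates 2 and 3 at 1% O2. This points to a structure among those libraries beside oxygen. Between these 3 libraries and the other shFACT libraries the median log2 difference was -0.01 in the shortest of 10 length groups of genes. In the longest it was -0.19, so the structure went along with gene length.

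For the interactions 100 groupings were drawn. With shHIF-1α 1 of 100 gave as many calls (real 3445, highest other 3029), which argues against a chance arrangement of these libraries there. With shFACT 8 of 100 did (6594 and 11212) and with shRNF20/40 10 of 100 (5307 and 9565), so it cannot be excluded by that count. The largest groupings kept all 3 knockdown libraries at 1% O2 and 1 of 3 at 20% O2 together, which turns the difference between subclones into an interaction. With each subclone's mean removed first, 1 of 100 gave as many calls with shHIF-1α (3326 and 2), shFACT (6583 and 4473) and shRNF20/40 (5230 and 634). That measure argues against a chance arrangement of these libraries, though the means were removed by the real subclone labels. With 1 subclone per knockdown, no grouping of libraries can exclude a chance difference between subclones.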
